A study of Mus musculus with 6 samples.

How the data were processed

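RNA of 3 wild-type and 3 Lgi1 knock-out samples of immortalized neural precursor-like cells was measured on Affymetrix Mouse Gene 1.0 ST arrays, 1 sample per array and 1 colour. Per the labels' protocols, total RNA was extracted with Trizol and biotinylated cDNA was made from it. The deposited table holds 1 value per probe set and array on a log2 scale, as judged from its range. The quartiles were nearly the same on all arrays, as they would be after a scaling of the arrays to one another. Partek is named in the submitters' processing notes with no version. The background correction, normalization, summarization of probes and filters behind the deposited log2 values are not given in the sources used here. The method of any scaling between arrays before deposit is therefore unknown. The deposited values were used without a further transformation or normalization. The genotype and the replicate number of each sample were taken from its title, and no sample was left out.

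The table had 35556 probe sets. GEO's platform annotation gave 1 gene symbol to 21789 of them, several to 1621 and none to 12146. Of those with 1 symbol, 21698 matched the reference gene table (assembly GRCm38.p6) by gene ID, and no symbol needed an update. That table was used only for names, chromosomes and the order of neighbouring genes, since the build behind the array annotation is not given in the sources used here. Of several probe sets of a gene the one with the highest mean over the 6 arrays was kept, which applied to 999 genes with up to 77 probe sets. This left 19938 genes, of which 19900 had a chromosome.

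Knock-out and wild-type arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, 4 residual degrees of freedom before moderation), and p-values were adjusted by the Benjamini-Hochberg method over all genes. A gene is said to have changed, risen or fallen at an adjusted p under 0.05, and 7720 genes had an unadjusted p under 0.05. Fold changes are knock-out minus wild type on the log2 scale, with the moderated SE. For gene lists, limma's camera with a preset correlation of 0.01 compared each list with all other genes, adjusted over the 41 lists. Beside it stand camera with a correlation estimated from the residuals, and fry, whose directional p tests whether the members move on balance one way. Chromosomes with at least 20 genes were tested with camera in the same way, 20 in all. Each list was also adjusted over its own members alone. Medians by chromosome are given for genes whose mean over the 6 arrays is above the median of all genes, since dim genes cannot show a shift.

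The test, the 41 lists, the rule for named genes and the alternatives were fixed before the data were examined, except that the fits without chromosomes X, Y, 14 and 19 and with chromosome medians subtracted, and the lists of escape and imprinted genes, were chosen after the data were seen. The rule took Lgi1, the 15 largest rises and 15 largest falls among genes that passed and whose arrays did not overlap between genotypes (predicted genes, olfactory and vomeronasal receptors and small RNA genes excepted), and the 4 members with the largest change of each list described. It gave 183 genes, of which 172 passed. The use of olfactory and vomeronasal receptor genes as a measure of background was chosen after the data were seen. The lists hold markers of cell types, guidance genes, receptors and channels, matrix genes, signalling pathways, regional transcription factors, stress and immune genes and the neighbours of Lgi1.

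The titles give both genotypes the replicate numbers 1 to 3. Deviations from the genotype means correlated at 0.19 to 0.29 across genes between arrays of the same number and at −0.18 to −0.0047 between arrays of different numbers (3 and 6 pairs; genes are not independent replicates). By a rule set beforehand, the numbers count as pairs when every same-number pair exceeds 0.1, and they met it. The main tests reported here were nonetheless fixed without a block, so their p-values leave this pairing out. A fit with the replicate number as a block was among the alternatives set beforehand. It called 7000 genes, 6279 of them among the 6296 of the main test, and 7 lists against 9. Its value stands beside each result whose call it changes.

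The other alternatives were quantile normalization, centring each array on its median, filters at the 25th percentile and at the median of mean expression, averaging or keeping all probe sets, an intensity trend with robust settings, array weights, no moderation, each array left out in turn, other set tests and other thresholds. The steps were tested on simulated data with the 19938 genes and 6 arrays of this comparison. Of 50 genes changed at each size, the test recovered 82% at 0.5, 94% at 1, 100% at 2 and 100% at 4 on the log2 scale, and 6 unchanged genes were called. None of the 40 simulated lists without a shift was called by camera, with either correlation, or by fry, and the shifted list was called by each. The simulated noise was independent between genes, and the lists without a shift held only unchanged genes. In the data 31.6% of genes changed, so the simulation does not show how often these tests call lists of correlated or widely changed genes. Arrays give no read depth, so the signal over background and the number of arrays set what can be seen. Probe sets with no symbol or several symbols were left out of the gene tests.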

Results

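Total RNA was profiled from immortalized neural precursor-like cells of mouse embryos that either were wild type for Lgi1 or carried a homozygous deletion of it. Lgi1 encodes a secreted neuronal protein that binds receptors of the ADAM family at synapses, and its loss causes epilepsy in mice and people. The cells came from the brains of C57BL/6J embryos at day 13.5 and were grown, once immortalized, in RPMI medium with a low share of serum. Each genotype was measured on 3 Affymetrix Mouse Gene 1.0 ST arrays, a platform whose probes lie along the whole length of a transcript. The labels call the arrays of a genotype biological replicates and do not give the number of embryos or lines behind them, so the p-values measure the spread between these samples, which may be technical. The median log2 value lay between 6.36 and 6.41 on all 6 arrays. Pearson correlations over all 35556 probe sets were 0.993 to 0.995 between arrays of a genotype and 0.968 to 0.971 between genotypes. The single comparison set knock-out against wild-type cells and asked which transcripts differ between them.

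Lgi1 itself (probe set 10462912, chromosome 19) lay at background level in both genotypes. Its log2 values were 4.61, 4.75 and 4.94 on the wild-type arrays and 4.53, 4.57 and 4.54 on the knock-out arrays, with means of 4.77 ± 0.168 and 4.55 ± 0.0211 (SD, n = 3 each). As a measure of background, 1194 olfactory and vomeronasal receptor genes, which act in the nose, had a median of 4.89 and a 95th percentile of 5.68. The log2 fold change of Lgi1 was −0.22 (SE 0.08) and did not pass the test (limma adjusted p = 0.075). With the replicate number as a block the same difference passed (adjusted p = 0.046), as it did without wild-type replicate 1 (log2 −0.30, adjusted p = 0.018). Without wild-type replicate 3 the log2 fold change was −0.13 (adjusted p = 0.23), and the adjusted p ranged from 0.018 to 0.23 over the alternatives. Because the signal did not rise above background even in wild-type cells, and the labels do not give the deleted part of the gene, Lgi1 did not serve as a check of the genotype labels.

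The genotypes differed across a large part of the transcriptome. Of 19938 genes tested, 6296 changed (31.6%), of which 2784 were higher and 3512 lower in knock-out cells. At least 2-fold changes were found for 608 higher and 453 lower genes, and 65 genes rose and 17 fell at least 16-fold. The largest rises were those of Sfrp2, a secreted modulator of Wnt signalling, from 5.47 ± 0.0323 to 13.28 ± 0.062 (SD, n = 3 each; log2 fold change +7.82, SE 0.06), and of Aspn, a small leucine-rich matrix proteoglycan (+7.81, SE 0.12). Sox2, the transcription factor that maintains neural progenitors, had the largest fall, from 11.26 ± 0.106 to 5.35 ± 0.173 (log2 fold change −5.92, SE 0.09, adjusted p = 3.3e-11). The 3 arrays of one genotype all lay above the 3 of the other for 1060 of the 1061 genes changed at least 2-fold, and for 42.3% of all genes, where chance gives 10%. Of the genes at least 2-fold higher, 202 had a wild-type mean under 5.68, and 135 of those at least 2-fold lower had a knock-out mean under it, so background limits these folds.

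Xist and 12 further genes made up the rest of the 15 largest rises. Mmp2, a gelatinase, rose by 6.13 on the log2 scale, Adamts5, an aggrecan-degrading protease, by 6.16, Thbs2, a matricellular protein, by 6.07 and Ddr2, a collagen receptor kinase, by 5.88. Abi3bp (+6.19), Cpxm2 (+5.92), Palmd (+6.35), Car3, a carbonic anhydrase (+6.59), and Rspo2, an R-spondin that amplifies Wnt signalling (+5.98), rose by similar amounts. The transcription factors Pou3f4 (+6.43) and Foxp2 (+6.00), the receptor-type phosphatase Ptprz1 (+6.43) and Xist, the non-coding RNA of the inactive X chromosome (+7.80), rose as well. The wild-type means of Sfrp2, Aspn, Xist, Car3, Pou3f4, Ptprz1, Palmd, Foxp2, Rspo2 and Cpxm2 lay under 5.68. Among the falls were the paired midbrain and hindbrain regulators En2 (−5.05, SE 0.07) and En1 (−4.70, SE 0.08), and the Y-linked genes Eif2s3y (−5.51) and Uty (−5.21). Epb41l4a (−5.66), Mgst1, a microsomal glutathione transferase (−4.65), Rab3b (−4.56), Podxl (−4.42), Mal2 (−4.37), Gnai1 (−4.25), Skida1 (−4.25), Cp, or ceruloplasmin (−4.23), Dtna (−4.21) and Chsy3, a chondroitin synthase (−4.16), completed the 15 largest falls. The knock-out means of Sox2, Epb41l4a, Eif2s3y, Uty, En2, En1, Mgst1, Podxl, Dtna and Chsy3 lay under 5.68.

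**Figure D1:**
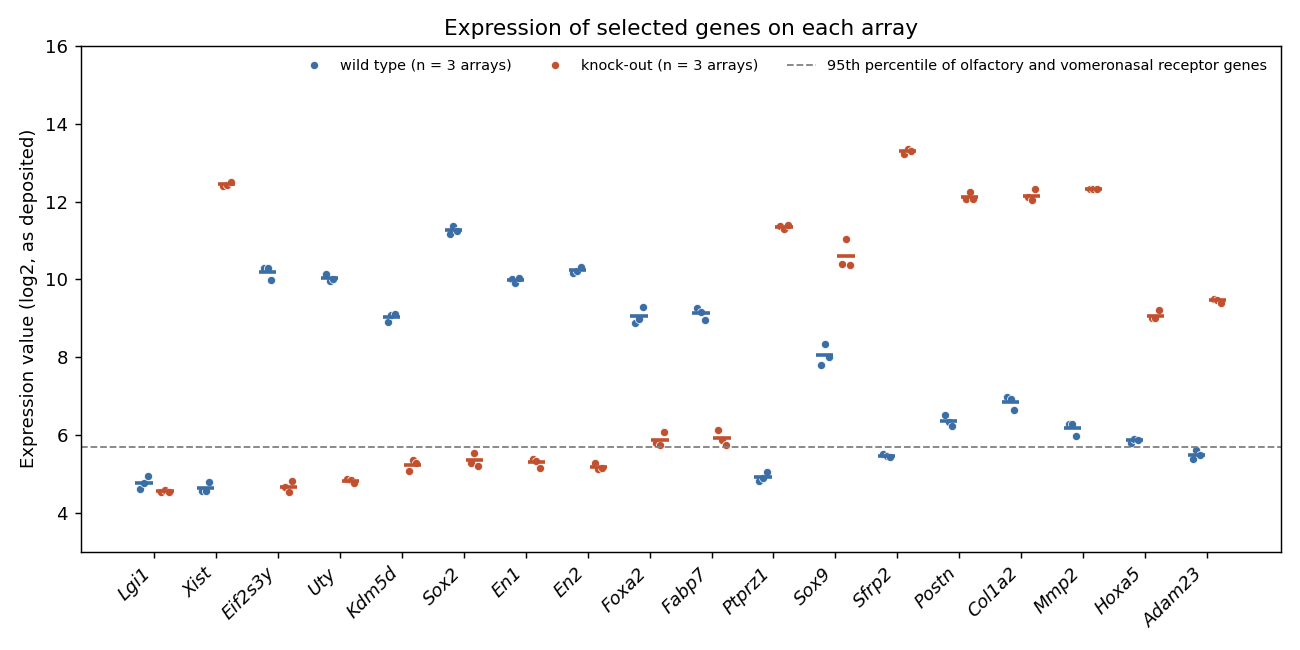
Log2 expression values as deposited of 18 named genes, with wild-type arrays in blue and knock-out arrays in red (n = 3 each); dots are arrays, short bars are group means and the dashed line is the 95th percentile of olfactory and vomeronasal receptor genes (5.68). Lgi1 lies under the dashed line in both genotypes, whereas the group means of the other 17 genes differ by 2.56 (Sox9) or more.

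Genes of the sex chromosomes separated the genotypes on every array. Xist had a mean of 4.64 in wild-type and 12.44 in knock-out cells, and Eif2s3y fell from 10.19 to 4.67, Uty from 10.03 to 4.82 and Kdm5d from 9.04 to 5.24 (log2 fold change −3.80). All 4 measured members of the list of Y-linked and X-inactivation genes changed, 1 upward and 3 downward, and the counts adjusted over the list alone were the same. The list passed as lower (camera adjusted p = 0.0364). It did not pass with an estimated correlation (adjusted p = 0.302) or with the replicate number as a block (adjusted p = 0.057), and its adjusted p ranged from 5e-06 (fry) to 0.86 over the alternatives. Because the list joins Xist, which rose, with Y-linked genes, which fell, a test of 1 direction does not measure how far the genotypes differ. Each of the 4 genes had a limma adjusted p of 3.7e-10 or less.

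Markers of fibroblasts and meninges rose as a group. Of 23 measured members, 20 rose, none fell and 3 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of +1.28. Postn, a matricellular protein of fibroblasts, rose by 5.77 (from 6.36 to 12.12), Col1a2, a chain of type I collagen, by 5.30, the surface glycoprotein Thy1 by 3.72 and Fbln2 by 3.50. The list had the lowest adjusted p of the 41 lists (camera, 8.6e-17), and its call was lost with the correlation between genes estimated from the data (adjusted p = 0.0786 with an estimated correlation). No list kept its call in camera with an estimated correlation, where 0.0786 was the lowest adjusted p and 6 lists had an unadjusted p under 0.05, against 9 calls with the preset correlation and 26 with fry. These arrays also differed in Xist and in the Y-linked genes, as did the arrays behind every group described here.

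Genes of the extracellular matrix moved in both directions with more rises than falls. Of 37 measured members, 18 rose and 9 fell, as they did adjusted over the list alone (camera adjusted p = 1.2e-04, higher; adjusted p = 0.302 with an estimated correlation). Nid1, which links basement membrane laminin and collagen, rose by 3.78 and Col6a3 by 2.97, beside Thbs2, while the laminin chain Lama5 fell by 2.92. Among matrix metalloproteinases and their inhibitors 10 of 26 rose and 5 fell (10 and 7 adjusted over the list alone), and the list did not pass (adjusted p = 0.106). It passed among genes above the 25th percentile (adjusted p = 0.043) and above the median level (adjusted p = 0.00013), with a range of 1.5e-05 (fry) to 0.51 over the alternatives. Besides Adamts5 and Mmp2, its largest changes were those of Adamts1 (+4.72) and Mmp23 (+3.98). Integrins, the receptors for matrix proteins, did not pass as a list either (7 of 19 rose and 4 fell, 8 and 4 adjusted over the list alone, adjusted p = 0.219). The collagen-binding integrin chains Itga2 (+5.33) and Itga1 (+2.69) rose with Itga8 (+2.48), and the laminin-binding chain Itga3 fell (−2.85). Cadherins split into 6 rises and 9 falls of 28 (the same adjusted over the list alone, adjusted p = 0.669), where the mesenchymal cadherin Cdh11 rose by 2.51 and Pcdh9 by 1.97, and the neural cadherin Cdh2 (−1.95) and Pcdh18 (−1.31) fell. Of 38 regulators of the actin cytoskeleton 8 rose and 14 fell (9 and 14 adjusted over the list alone, adjusted p = 0.688), with Rac3 (+2.14) and Rnd3 (+1.34) among the rises.

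The lists of Wnt and TGF-β pathway genes passed as higher, which concerns the RNA of their members and not the activity of the pathways. Of 45 Wnt pathway genes 18 rose and 7 fell (19 and 7 adjusted over the list alone, camera adjusted p = 7.7e-05, and adjusted p = 0.277 with an estimated correlation). The median log2 fold change of the Wnt list was +0.06 and its mean +1.01, with 13 members at least 2-fold higher and 1 lower. Its largest members were Sfrp2, Rspo2, Rspo3 (+4.99), a further secreted amplifier, and Lgr5, a receptor of R-spondins (+5.15). Of 32 TGF-β and BMP pathway genes 19 rose and 4 fell (20 and 4 adjusted over the list alone, camera adjusted p = 8.6e-06, and adjusted p = 0.114 with an estimated correlation). The median of that list was +0.43 and its mean +0.59. Fst, an extracellular inhibitor of activins, rose by 2.53, the ligands Tgfb3 and Bmp6 rose by 2.31 and 2.05, and Ltbp1, which binds latent TGF-β, fell by 1.53. The Hedgehog list did not pass (5 of 13 higher and 1 lower, 5 and 2 adjusted over the list alone, adjusted p = 0.069), although the co-receptors Gas1 (+3.88) and Boc (+2.33) rose and the receptor Ptch1 fell (−0.83). The Hedgehog list passed without wild-type replicate 2 (adjusted p = 0.049) and with chromosomes X, Y, 14 and 19 left out, as chosen after the data were seen (adjusted p = 0.029). Its range was 0.00013 (fry) to 0.3 over the alternatives. The Notch list did not pass (6 of 22 higher and 8 lower, 7 and 8 adjusted over the list alone, adjusted p = 0.936), in which the ligand Jag1 rose by 2.20 and Dtx4 fell by 2.24. FGF and EGF family genes gave 12 rises and 7 falls of 32 (13 and 7 adjusted over the list alone, adjusted p = 0.187), from Fgf18 (+3.69) to Fgf7 (−2.88).

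Regional identity genes rose and fell. The Hox genes, which pattern the hindbrain and spinal cord and are silent in more anterior brain, showed 14 rises and no fall among 32 (the same adjusted over the list alone, camera adjusted p = 8.3e-07; adjusted p = 0.0786 with an estimated correlation). Hoxa2 rose by 3.45, Hoxa5 by 3.21, Hoxa6 by 3.01 and Hoxa10 by 2.28. Among 20 transcription factors of the midbrain and hindbrain, 6 rose and 4 fell (6 and 5 adjusted over the list alone, adjusted p = 0.936). Beside En1 and En2, the floor plate factor Foxa2 fell by 3.18, from 9.05 to 5.87, whereas Zic2 rose by 5.13. The median (−0.0052) and mean (−0.13) of this list were below 0 while camera gave the upward direction. Forebrain factors gave 6 rises and 4 falls of 20 (the same adjusted over the list alone, adjusted p = 0.272), with rises of Ebf1 (+5.36), Meis2 (+2.14) and Dlx5 (+2.11) and a fall of Lhx2 (−1.13). The knock-out arrays, on which En1 and En2 lay under 5.68, were also the arrays with high Xist.

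Neural progenitor and radial glia markers included large falls and large rises. Of 25 measured members 5 rose and 8 fell, 3 and 6 of them at least 2-fold (the same calls adjusted over the list alone). The list did not pass against other genes in camera (adjusted p = 0.452), and fry, which called 26 of the 41 lists, gave a downward direction (adjusted p = 0.00286). Sox2 and the radial glial fatty acid binding protein Fabp7 (−3.21, SE 0.11) fell, and Ptprz1 and Sox9 (+2.56, SE 0.18) rose. Neuron markers were mostly not called (2 of 26 higher and 2 lower, the same adjusted over the list alone, adjusted p = 0.759), with Nsg1 (+1.06) and Map2 (+0.90) higher and Syt1 (−0.92) lower. Among 14 astrocyte markers 5 rose and 2 fell (5 and 3 adjusted over the list alone, adjusted p = 0.458), and the water channel Aqp4 (−2.10) and Fgfr3 (−1.19) fell, while Sparcl1 rose by 1.02. Of 15 oligodendrocyte lineage markers 3 rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.688). The largest change was that of Pdgfra (+3.06), a receptor that fibroblasts carry as well as oligodendrocyte precursors, and Mbp fell by 0.87. Microglia and leukocyte markers were called for 2 of 16 members (1 higher and 1 lower, the same adjusted over the list alone, adjusted p = 0.905). These were Tmem119 (+2.12), known also from cells of the osteoblast lineage, and Trem2 (−0.23).

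Endothelial markers passed as higher, with 5 of 14 members higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 0.0391; adjusted p = 0.482 with an estimated correlation). The transcription factor Erg rose by 4.60, the angiopoietin receptor Tek by 3.14, Eng by 0.82 and Ramp2 by 0.45. With the replicate number as a block the list did not pass (adjusted p = 0.051), nor did it without wild-type replicate 3 (adjusted p = 0.089), and its adjusted p ranged from 0.00035 (fry) to 0.48 over the alternatives. Pericyte and smooth muscle markers did not pass (5 of 13 higher and 2 lower, the same adjusted over the list alone, adjusted p = 0.106), though Cnn1, a smooth muscle calponin, rose by 4.65, Anpep by 2.31, Rgs5 by 1.29 and Myl9 by 1.23. Among genes above the 25th percentile that list passed (adjusted p = 0.036), with a range of 2.4e-05 (fry) to 0.4 over the alternatives. Of 13 neural crest and Schwann cell markers 2 rose and 4 fell (the same adjusted over the list alone, adjusted p = 0.695), with a rise of Snai2 (+3.05), a factor of epithelial to mesenchymal transition, and falls of Ets1 (−0.92) and Tfap2a (−0.70). The medians of the oligodendrocyte (−0.015), microglia (−0.019) and neural crest lists (−0.074) lay below 0 and their means above it, and camera gave the first 2 the upward direction.

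**Figure D2:**
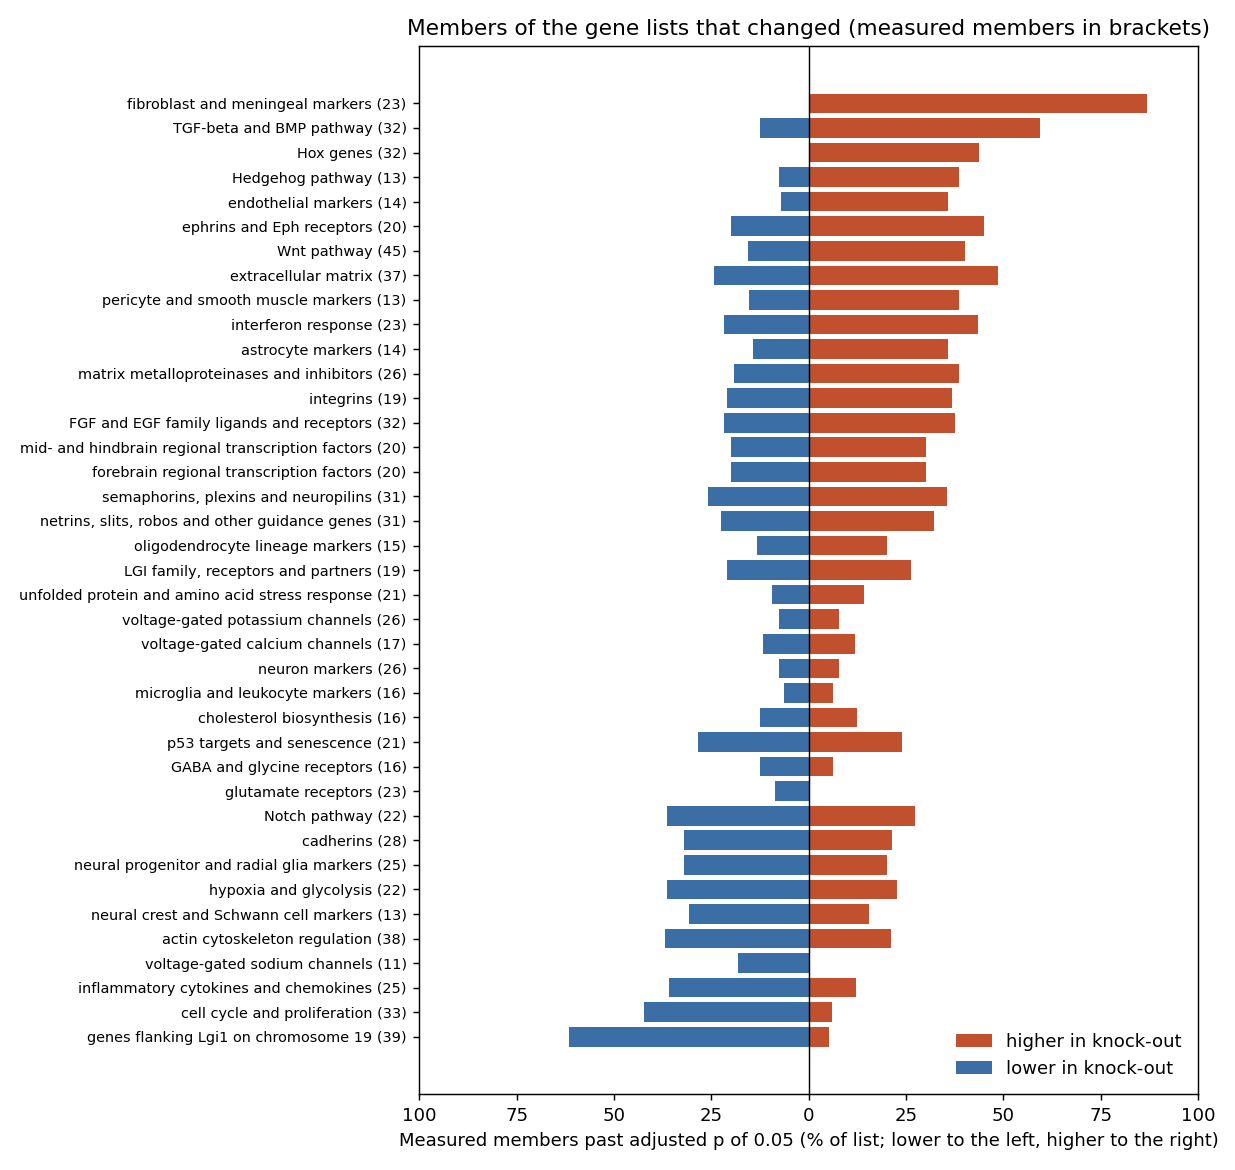
Share of the measured members of each gene list that were higher (red, to the right) or lower (blue, to the left) in knock-out cells at a limma adjusted p under 0.05, in percent of the list, with the number of measured members in brackets; lists with at least 10 measured members are drawn. Fibroblast and meningeal markers have the largest share of rises (20 of 23) and genes flanking Lgi1 the largest share of falls (24 of 39).

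Axon guidance genes rose and fell, with more rises in each of 3 lists. None of these lists passed against other genes in camera, while fry, which tests whether members move on balance one way, gave an upward direction for semaphorins, plexins and neuropilins (adjusted p = 0.00165), ephrins and Eph receptors (adjusted p = 0.0014) and the netrin, slit and robo list (adjusted p = 0.000614). Fry called 26 of the 41 lists and does not compare a list with other genes. Its values therefore show nothing particular to guidance genes. Semaphorins, plexins and neuropilins gave 11 rises and 8 falls of 31 (the same adjusted over the list alone, camera adjusted p = 0.272). Plxna2, a semaphorin receptor, rose by 4.03, the repulsive ligands Sema3a and Sema3d by 2.69 and 2.30, and Sema3c fell by 2.62. Among 20 ephrins and Eph receptors 9 rose and 4 fell (9 and 5 adjusted over the list alone, adjusted p = 0.380), led by Efna5 (+2.49), Epha4 (−2.30), Efna2 (+1.41) and Ephb6 (−1.38). Netrins, slits, robos and related genes gave 10 rises and 7 falls of 31 (the same adjusted over the list alone, adjusted p = 0.363), led by the netrin receptor Unc5c (+3.01), Slit3 (+2.83), Srgap1 (+2.79) and Robo2 (+2.35). Of the LGI family with its receptors and partners, 5 of 19 rose and 4 fell (6 and 5 adjusted over the list alone, adjusted p = 0.668). Adam23, a receptor of LGI1, rose from 5.49 to 9.46 (log2 fold change +3.96, SE 0.07), and Kcnab1, a potassium channel subunit, fell by 3.22. Dlg4, the postsynaptic scaffold PSD-95, fell by 0.56 and Lin7a rose by 0.51.

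Receptors and channels of neurons were mostly not called. Some members lay under 5.68 in wild-type and knock-out cells, such as Grm8 (4.81 and 4.67), Gabra4 (4.57 and 4.73) and Scn9a (5.25 and 5.10). For such genes the lack of a call is no evidence that they did not change. Grik5 and Scn2a lay above that level and were not called either. Of 23 glutamate receptor genes none rose and 2 fell (the same adjusted over the list alone, adjusted p = 0.936), Gria4 (−0.38) and Gria1 (−0.30), with all group means of these 2 genes under 5.68. GABA and glycine receptors gave 1 rise, of Glrb (+1.89), and 2 falls of 16, Gabra3 (−0.77) and Gabbr1 (−0.67), with the same counts adjusted over the list alone (adjusted p = 0.713). Potassium channels gave 2 rises and 2 falls of 26 (2 and 1 adjusted over the list alone, adjusted p = 0.936), with Kcnc2 higher (+3.96) and Kcnh7 lower (−1.80). The median of that list was −0.035 and its mean +0.08, with the upward direction in camera. Of 17 calcium channel genes 2 rose, Cacna1g (+1.03) and Cacnb1 (+0.61), and 2 fell, Cacna1a (−0.93) and Cacna2d1 (−0.87), and adjusting over the list alone gave the same counts (adjusted p = 0.936). Sodium channels had 2 falls of 11, Scn7a (−1.83) and Scn3a (−1.60), in both adjustments, the list alone included (adjusted p = 0.323).

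Cell cycle genes passed as lower, by small amounts. Of 33 measured members 2 rose and 14 fell (2 and 16 adjusted over the list alone), with a median log2 fold change of −0.17 (camera adjusted p = 0.0137; adjusted p = 0.279 with an estimated correlation). The list did not pass among genes above the median level (adjusted p = 0.078), and its adjusted p ranged from 0.00057 (fry) to 0.28 over the alternatives. Ccnd2, a D-type cyclin (−1.05), the replication helicase subunit Mcm7 (−0.49) and Ccnb2 (−0.42) fell, and Ccne1 rose by 0.41. Of 21 p53 targets and senescence genes 5 rose and 6 fell (6 and 6 adjusted over the list alone, adjusted p = 0.936), with Plk2 higher (+1.20) and Gadd45a lower (−1.15). Its median (−0.050) and mean (+0.01) differed in sign, and camera gave the downward direction. Interferon response genes gave 10 rises and 5 falls of 23 (the same adjusted over the list alone) and did not pass (adjusted p = 0.106), with Rtp4 (+2.64), Ifit1 (+1.60) and Oasl2 (+1.51) higher and the chemokine Cxcl10 lower (−1.65). Among inflammatory cytokines and chemokines 3 of 25 rose and 9 fell (3 and 10 adjusted over the list alone, adjusted p = 0.223). Ptgs2, the inducible cyclooxygenase (−3.46), and the chemokines Ccl2 (−1.85) and Ccl7 (−1.40) fell, and Ccl5 rose by 1.82. That list passed among genes above the median level (adjusted p = 0.046), with a range of 0.00018 (fry) to 0.51 over the alternatives. Antigen presentation genes gave 1 rise and 1 fall of 8 (Tap1 +0.61 and Tapbp −0.61, the same adjusted over the list alone, adjusted p = 0.848).

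Metabolic and stress lists did not pass. Hypoxia and glycolysis genes gave 5 rises and 8 falls of 22 (5 and 9 adjusted over the list alone, adjusted p = 0.458), with Adm higher (+2.26) and the glycolytic enzyme Pgk1 lower (−0.82). Cholesterol synthesis genes gave 2 rises, Sqle (+0.36) and Fdft1 (+0.35), and 2 falls, Idi1 (−0.34) and Nsdhl (−0.34), of 16, as they did adjusted over the list alone (adjusted p = 0.458). The unfolded protein and amino acid stress list gave 3 rises and 2 falls of 21 (the same adjusted over the list alone, adjusted p = 0.383), with Xbp1 higher (+0.59) and the cystine transporter gene Slc7a11 lower (−1.08).

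Genes on chromosomes 14 and 19 shifted together. Among genes above the median level of all genes, the 341 on chromosome 14 had a median log2 fold change of +0.41 (quartiles 0.22 and 0.63), and 88.3% of them lay above 0. The 353 on chromosome 19 had a median of −0.25 (quartiles −0.47 and −0.04), and 78.8% lay below 0. Over all genes, dim ones included, the medians were +0.115 (699 genes) and −0.0895 (675 genes). On the other 17 autosomes the medians of genes above the median level lay between −0.20 and +0.10. Over all genes of a chromosome, 287 rose and 32 fell on chromosome 14 (camera adjusted p = 7.99e-11; adjusted p = 0.0267 with an estimated correlation), and 52 rose and 220 fell on chromosome 19 (adjusted p = 0.000728; adjusted p = 0.0304 with an estimated correlation). Chromosomes 14 and 19 passed in all 15 alternatives in which they were tested. Chromosome 9 passed as lower (median −0.20, adjusted p = 0.0414; adjusted p = 0.0267 with an estimated correlation). Chromosomes 1, 7 and 10 passed as higher with medians of +0.09, +0.10 and +0.06 (adjusted p = 0.0414 each), and not with an estimated correlation (adjusted p = 0.109, 0.0515 and 0.0599). These 4 chromosomes lost their calls without wild-type replicate 3 (adjusted p = 0.0545 each) and without knock-out replicate 1 (adjusted p = 0.0562 each). Chromosome 7 also lost its call without wild-type replicate 2 (adjusted p = 0.0567) or knock-out replicate 2 (adjusted p = 0.0576), and chromosome 10 without wild-type replicate 1 (adjusted p = 0.0542) or knock-out replicate 3 (adjusted p = 0.0531). The X chromosome did not pass (median −0.19, adjusted p = 0.187).

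Genes that flank Lgi1 on chromosome 19 fell as a list. Of 39 measured neighbours 24 fell and 2 rose (25 and 2 adjusted over the list alone), with a median log2 fold change of −0.34 (camera adjusted p = 1.6e-06; adjusted p = 0.0786 with an estimated correlation). The largest falls were those of Exoc6, a subunit of the exocyst complex (−2.27), the fatty acid receptor gene Ffar4 (−2.05), the translational regulator Cpeb3 (−1.73) and the retinol carrier Rbp4 (−1.34). After the median shift of each chromosome was subtracted, an alternative chosen after the data were seen, the list did not pass (adjusted p = 0.10), and over its alternatives the adjusted p ranged from 6.6e-07 to 0.10.

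**Figure D3:**
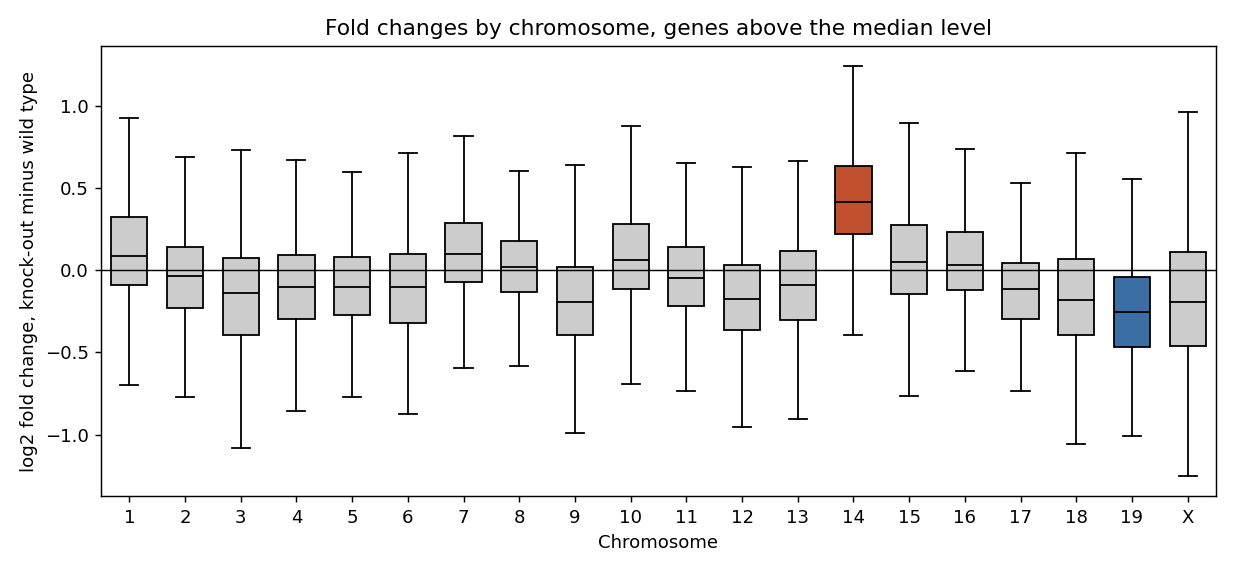
Log2 fold changes (knock-out minus wild type, vertical axis) of genes above the median expression level, by chromosome; boxes span the quartiles with the median as a line, whiskers reach the last gene within 1.5 times the box height, and genes beyond them are not drawn. Chromosome 14 (red, median +0.41) lies above and chromosome 19 (blue, median −0.25) below the other autosomes.

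The 6296 changed genes rest on 3 arrays per genotype, with a median SE of 0.0715 for a log2 fold change, and the number of arrays limits the precision. Genotype coincides with the levels of Xist and the Y-linked genes on all 6 arrays, and the shifts of chromosomes 14 and 19 are differences between the same 2 groups. No gene's change can therefore be assigned to one of them by this design. With chromosomes X, Y, 14 and 19 left out, as chosen after the data were seen, 5416 genes changed, 926 of them at least 2-fold. That count shows that most changed genes lie on other chromosomes, and it does not separate their changes from the sex or chromosome differences.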

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

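The tests of Xist, of the share of genes by direction and of blocks along chromosomes 14 and 19, of the genes flanking Lgi1 and of mixed or different cells were chosen after the results were seen; the list and test of escape genes were chosen after the Xist and Y-linked values, though before those of the escape genes, and the test of a length or level trend after the chromosome shifts, though before its own result, while the counts of other splits were set beforehand. The 13767 probe sets with no or several gene symbols entered none of the gene tests, only the alternative that kept all probe sets. Adjusted over these probe sets alone, 508 changed between the genotypes (291 higher and 217 lower, 154 of them at least 2-fold). That is a smaller share than the 31.6% of genes that changed. Of the 508, 428 have no symbol and 80 have several.

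In the knock-out cells Xist was high and the Y-linked genes were at background, and in the wild-type cells the reverse held. Loss of the Y chromosome from male knock-out cells leaves Xist silent, and the log2 fold change of Xist of 7.80 (SE 0.078) argues against it. Cells with 2 X chromosomes would raise the genes that escape X inactivation, and the median log2 fold change of 8 such genes exceeded that of 311 other X-linked genes above the median level by 0.402 (0.207 against −0.195, permutation p = 0.021). Of the 8 genes 4 rose and 2 fell (Usp9x −0.40 and Utp14a −0.33). As a list they did not pass camera (p = 0.066, and p = 0.145 with an estimated correlation). Without the matrix gene Bgn the difference was 0.314 (permutation p = 0.091), so the escape genes alone are weak evidence that rests in part on 1 gene. The main evidence for 2 X chromosomes is Xist, the RNA of the inactive X chromosome, with a mean of 12.44 in knock-out cells while the Y-linked genes lay at background. All 3 measured Y-linked genes lay at background together with high Xist on every knock-out array, which marks a difference of sex between the cells. These values argue against an effect of the deletion as the source of the Xist and Y-linked differences. An effect of the deletion on other sex chromosome genes has no test of its own here, and sex coincides with genotype on every array.

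Chromosome 14 genes were higher and chromosome 19 genes lower in knock-out cells. A few strongly changed genes would leave the rest near 0, whereas 88.3% of chromosome 14 genes above the median level lay above 0 and 78.8% of those on chromosome 19 below it, against at most 64.8% above and at most 73.2% below on the other autosomes. The shares show that most of these genes moved one way. Both chromosomes were picked after their shifts were seen, so lying beyond the other autosomes is not independent support. Chromosome 9, with 73.2% below 0, lay near chromosome 19. After a trend on gene length and expression level was subtracted, the median of chromosome 14 was 0.406 (bootstrap SE 0.02; 0.413 before), which argues against such a trend. A dosage difference of whole chromosomes between the lines stays open: copy number was not measured, and although 20 of 20 blocks of consecutive genes had the sign of their chromosome, 99.8% of 1000 random gene orders gave the same count, so the blocks decide nothing. The genes flanking Lgi1 lay lower than the other chromosome 19 genes, by −0.232 in the median (25 and 328 genes, permutation p = 0.0037), but 21 of 278 windows of 25 consecutive genes elsewhere on the chromosome lay as low (7.55%) and the list did not pass with chromosome medians subtracted (adjusted p = 0.10), so a local effect of the deletion and a broader low stretch cannot be told apart.

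Of 23 fibroblast and meningeal markers 20 were higher in knock-out cells (camera adjusted p = 8.6e-17; adjusted p = 0.0786 with an estimated correlation), and Sox2, En1, En2 and Foxa2 were lower. A minority of other cells mixed into the knock-out cultures would leave over 50% of the wild-type signal, but 126 genes fell by more than 2 on the log2 scale, which argues against it for the lowered genes; Sox2, whose knock-out mean lies under the background limit of 5.68, kept at most 1.66% of its wild-type level. For the raised genes, the 20 fibroblast and meningeal markers that rose had a median knock-out level of 9.14, and without a profile of pure fibroblasts an admixture and a change of the cells themselves cannot be told apart. The Y-linked genes (median log2 fold change −5.21, with a range within a genotype of at most 0.31) and Xist (+7.80) mark a difference in origin, that of sex, apart from the deletion. Whether a difference in origin underlies the mesenchymal and neural changes cannot be told apart from the genotype, because origin of that kind coincides with it on every array. An effect of the loss of Lgi1 stays open beside these.

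With 3 arrays per genotype there are 10 splits of the 6 arrays into equal groups, too few for a share under 0.05. The real split was the 1 of 10 with the most genes changed (6296, highest other 0), higher (2784 and 0), lower (3512 and 0) and changed at least 2-fold (1061 and 0), and also with the most gene lists (9, highest other 5) and chromosomes (6, highest other 2). Each other split puts both genotypes in both groups, so the large genotype difference widens the spread within the groups. The counts of the other splits therefore do not show how many calls would arise without a difference. The real split parts all 3 replicate pairs; the other 3 splits that do so gave at most 0 genes, 3 lists and 2 chromosomes, and the 6 that part 1 pair at most 0 genes, 5 lists and 2 chromosomes.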

How the results depend on the processing

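The fits without chromosomes X, Y, 14 and 19 and with chromosome medians subtracted were chosen after the results were seen; the other alternatives were planned. Counts of changed genes stayed within 1.5 times the reported counts except at a looser fold threshold, where 2119 genes changed at least 1.5-fold against 1061 at least 2-fold. The number changed ran from 4451 without moderation to 7000 with the replicate block, which found 6279 of the 6296 genes. Leaving out each array in turn gave 5485 to 5803 changed, 2442 to 2537 higher, 3012 to 3272 lower and 1053 to 1065 changed at least 2-fold. Lgi1 passed when arrays were centred on the median (−0.254, adjusted p = 0.04), with an intensity trend (−0.221, adjusted p = 0.046), with the replicate block (−0.221, adjusted p = 0.046) and without wild-type replicate 1 (−0.30; range −0.30 to −0.133 with each array left out; adjusted p 0.018 to 0.23 over all alternatives), and the filters on dim genes removed it. The replicate block also ended the calls of the endothelial and sex-linked lists (7 lists called) and changed no other call of a named gene, list or count. Called lists numbered 0 with an estimated correlation and 26 with fry, which does not compare a list with other genes, and 8 to 10 with each array left out: endothelial markers were lost without wild-type replicate 3 (adjusted p = 0.089) and the Hedgehog list was gained without wild-type replicate 2 (adjusted p = 0.049). The midbrain and hindbrain list turned downward under fry (adjusted p = 0.00035), and the sex-linked list turned upward with chromosome medians subtracted (adjusted p = 0.86), which removes the shift of the Y chromosome by construction. Keeping genes above the 25th percentile gained the metalloproteinase (adjusted p = 0.043) and pericyte lists (0.036) and ended the call of the sex-linked list (0.06); keeping those above the median gained the metalloproteinase (0.00013) and cytokine lists (0.046) and ended the calls of the cell cycle (0.078) and sex-linked lists (0.08). The sex-linked list was also lost with centred arrays (0.057) and camera on ranks (0.28), and the endothelial list on ranks (0.13). Without chromosomes X, Y, 14 and 19 the Hedgehog list passed (0.029), and with chromosome medians subtracted the endothelial (0.077) and flanking lists (0.10) did not. Called chromosomes numbered 12 among genes above the median, 3 with an estimated correlation and 2 to 5 with each array left out, with 2 without wild-type replicate 3 and 2 without knock-out replicate 1; the cause was not tested. Of 2694 values of 182 named genes under the alternatives, 2655 kept direction and side of the threshold, 28 lost the call, 11 gained it and 0 reversed. Signal over background sets the limit for dim genes such as Lgi1.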

Other observations

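The list of imprinted genes, expressed from only one parental copy, was composed after the results were seen, and so were its tests. Of 33 imprinted genes measured, 15 were higher and 5 lower in knock-out cells, with a median log2 fold change of +0.12 (camera p = 0.000953; p = 0.0315 with an estimated correlation). Mest rose by 5.36 on the log2 scale, from 7.55 to 12.91, Plagl1, a zinc finger regulator of other imprinted genes, by 4.67, the growth factor gene Igf2 by 4.37 and Asb4 by 3.56. The non-coding RNA Meg3 rose by 2.32, Peg3 by 1.70 and the cell cycle inhibitor gene Cdkn1c by 1.68. Nnat (−1.99), Ppp1r9a (−1.45), Rasgrf1 (−0.83) and Dlk1 (−0.77) fell. These genes were chosen after their values were seen.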
